A study of Gallus gallus with 6 samples.

How the data were processed

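RNA from 6 cultures of chicken neural crest cells was hybridised to an Affymetrix chicken array after labelling by in vitro transcription, per the labels' protocols. The titles name 3 biological replicates for each of 2 groups, v-Myb-L3,4A-HAER and v-Myb-L3,4A-N118D-HAER, and do not say whether these came from separate embryo pools, so p-values measure the spread between these cultures. The deposited table holds 1 log2 value per probe set and array, and GCRMA and Partek 6.4 are named for it per the submitters' processing notes. GCRMA corrects background by probe sequence, normalizes across arrays and summarises the probes of a set. The role of Partek and the probe set definition are not given in the sources used here. The scale was read as log2 from the values, which run from 0.78 to 15.83 with medians of 3.08 to 3.12 and none below 0, and genes were not centred. Scanner files were not used here, so the background correction could not be varied. Background correction by GCRMA pulls dim probe sets towards a common floor, which shrinks differences at low levels.

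The table held 38535 probe sets. The 96 AFFX control probe sets were left out, and 16526 of the remaining 38439 with a value of at least 4 on at least 3 of the 6 arrays were tested. 2 reporter probe sets were among those tested. Gene symbols came from the platform annotation, which can be old. It gave 27178 probe sets 1 symbol, 177 several and 11180 none, and the corresponding numbers among the tested probe sets were 13445, 67 and 3014. No gene was named from a probe set with several symbols or none.

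The groups were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, by lmFit and eBayes with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Differences are v-Myb minus N118D on the log2 scale, and standard errors and 95% confidence intervals use the moderated variance. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1. On simulated data with the variances of the 16526 probe sets and independent noise, the same test recovered 69.8% of planted log2 differences of 1. It recovered 92.6% of those of 2, with 4.36% false calls, and 5.03% of unchanged probe sets had an unadjusted p under 0.05. In the data 1.91% of the probe sets had such a p in limma. The simulation thus does not match the data, and its recovery rates may not hold for them.

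Gene lists, 21 in all, were fixed before the data were examined, as were the main test and the alternatives unless stated otherwise. They covered pigment cells, neural crest progenitors, the BMP pathway in 3 lists, reported Myb targets, the cell cycle, the glial, neuronal, mesenchymal, neural tube, muscle, cartilage, blood and endothelial cell types, stress, interferon, Wnt, Notch, TGF-beta and FGF genes. Of 331 genes listed, 287 had a probe set. 5 list symbols were matched to the annotation through synonyms. Lists were tested with camera at a preset correlation of 0.01 over 8571 genes, each represented by its probe set with the highest mean, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. A planted shift of 0.4 in the melanocyte list was recovered in 5 of 5 simulated runs with 0 other lists called. Genes were simulated as independent there, while the estimated correlation of that list in the data was 0.69. Those runs therefore do not show how the list test behaves on these data. A list of epithelial genes was added after the values had been seen.

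Genes were named by a rule fixed in advance. Where fewer than 12 genes passed the threshold in a direction, the 8 with the smallest unadjusted p and a fold of at least 1.5 were named, with MYB and up to 4 tested members of each list with the smallest p. Genes named outside that rule are said to be so. Alternatives were no filter, a filter at 6, quantile normalization, median centring, eBayes with trend and robust settings, no moderation, array weights, the replicate number as a block, a fold of at least 2, the mean of probe sets per gene, and leaving out each array. A neural gene score as a covariate and leaving out both arrays numbered 1 were added after seeing the data.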

Results

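Transcript levels were measured on 6 chicken gene expression arrays, 3 for each of 2 groups of cultured neural crest cells. Neural crest cells leave the dorsal neural tube of the embryo and give rise to pigment cells, peripheral neurons, glia and mesenchyme. The cells had migrated out of neural tubes of stage 10 to 13 embryos that were explanted into medium with retrovirus, and the explants were taken away after 3 days. In the first group (v-Myb arrays) the virus carried v-Myb-L3,4A-HAER, a form of the oncogenic transcription factor v-Myb with an altered leucine zipper and activity that depends on 4-OH-tamoxifen. In the other group (N118D arrays) the same protein also carried the N118D substitution in its DNA-binding domain. Both groups were treated for 4 hours with 4-OH-tamoxifen at 200 nM, so the comparison asks which transcripts differ between cells with the intact and the altered DNA-binding domain. No array lacked the treatment, so differences present before it cannot be told apart from those that followed it. Levels of the introduced proteins were not measured here. The deposited values are on a log2 scale, with array medians of 3.08 to 3.12 and 42.7% to 43.2% of probe sets at or above 4. The number of arrays, 3 per group, limits the precision of every difference given.

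Genes of the pigment cell lineage were on average higher in v-Myb cultures than in N118D cultures, with 18 of 19 measured melanoblast and melanocyte genes above. Their mean difference was 0.37 on the log2 scale, which was 0.10 without v-Myb replicate 2. These genes varied together (estimated correlation 0.69), so they do not count as separate observations. Their mean level in v-Myb replicate 1 lay below that in N118D replicates 2 and 3. A list of epithelial genes, chosen after the values were seen, was lower with a mean of -0.84, and its lowest level was on v-Myb replicate 2. Mean differences below 0 were measured for ligands, receptors and SMADs of the BMP pathway (-0.19, 9 of 11 genes lower), for mesenchymal and matrix genes (-0.12, 16 of 18) and for TGF-beta pathway genes (-0.12, 12 of 12). Leaving out 1 array took these means as near to 0 as -0.12, -0.04 and -0.04. Among single genes, SLC25A37, a mitochondrial iron importer, was higher in v-Myb cultures by 1.38 on one probe set and by 0.21 on another, and VNN2, a member of the vanin family, was 3.59-fold lower. None of the 16526 probe sets tested passed an adjusted p of 0.05 in limma, so the differences of single genes are given as values, and the 4 lists other than the epithelial one passed camera at its preset correlation but not with an estimated one.

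The smallest adjusted p in limma was 0.9999, and 315 probe sets had an unadjusted p under 0.05, 139 of them higher and 176 lower in v-Myb cultures. That is 1.91% of the probe sets, and 826 would be expected by chance. The 3 arrays of each group did not overlap for 948 probe sets, or 5.74%, where chance gives 10%. A difference of at least 2-fold was measured for 8 probe sets that were higher and 52 that were lower in v-Myb cultures, of which 3 and 17 had no overlap between the groups. These counts were 34 and 210 without v-Myb replicate 1, 9 and 19 without v-Myb replicate 2, 15 and 62 without v-Myb replicate 3, and 13 and 59 without N118D replicate 3. The median absolute difference was 0.07 with a median standard error of 0.13 on the log2 scale. On a first principal component that held 54.6% of the variance, v-Myb replicate 1 had a score of 0.66 and N118D replicate 1 of 0.38, against -0.46 to 0.02 for the other arrays. Leaving out v-Myb replicate 1 raised the count of unadjusted p under 0.05 to 1206, while the count was 176 without v-Myb replicate 2 and 565 without v-Myb replicate 3, and no probe set passed the adjusted threshold in any of these fits.

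Of the genes that were higher in v-Myb cultures, SLC25A37 had log2 levels of 9.19 ± 0.27 in v-Myb and 7.82 ± 0.32 in N118D cultures (SD, n = 3 each), a difference of 1.38 with a standard error of 0.21. The level of NKX3-2, a homeobox transcription factor, was 6.45 ± 0.29 against 5.13 ± 0.55 (SD, n = 3 each), a difference of 1.32 with a standard error of 0.30. PPP1R3B, a glycogen-targeting subunit of protein phosphatase 1, was higher by 0.99, and LCP1, an actin-bundling protein, by 0.85. Differences of 0.60 to 0.67 were measured for CACFD1, CFLAR, a regulator of caspase-8 activation, GATM, an enzyme of creatine synthesis, and CRYAB, a small heat shock protein. In all 8 genes every v-Myb array lay above every N118D array, which the choice by smallest p makes likely. A separate probe set for SLC25A37 was higher by only 0.21, and another for NKX3-2 stayed between 2.46 and 2.57 on all arrays and was not tested.

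Of the genes that were lower, VNN2 had log2 levels of 5.69 ± 0.55 in v-Myb and 7.54 ± 0.40 in N118D cultures (SD, n = 3 each), a difference of -1.84 with a standard error of 0.33, and its other tested probe set differed by -1.24. BMP5, a ligand of the BMP family, was at 5.31 ± 0.27 against 6.30 ± 0.24 (SD, n = 3 each), a difference of -0.99 with a standard error of 0.18. The homeobox genes HOXA5 and HOXB4 differed by -0.63 and -0.64. IFI27L2, which belongs to the interferon list, differed by -0.88, the keratin KRT13 by -0.68, the cell adhesion gene MPZL2 by -0.72, and RIN2, a Rab5-binding exchange factor, by -0.61. Every v-Myb array lay below every N118D array in these 8 genes, which were likewise chosen by smallest p. A separate probe set of RIN2 went the other way, with a difference of 0.07. All 16 genes had an adjusted p of 0.9999 in limma.

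**Figure D1:**
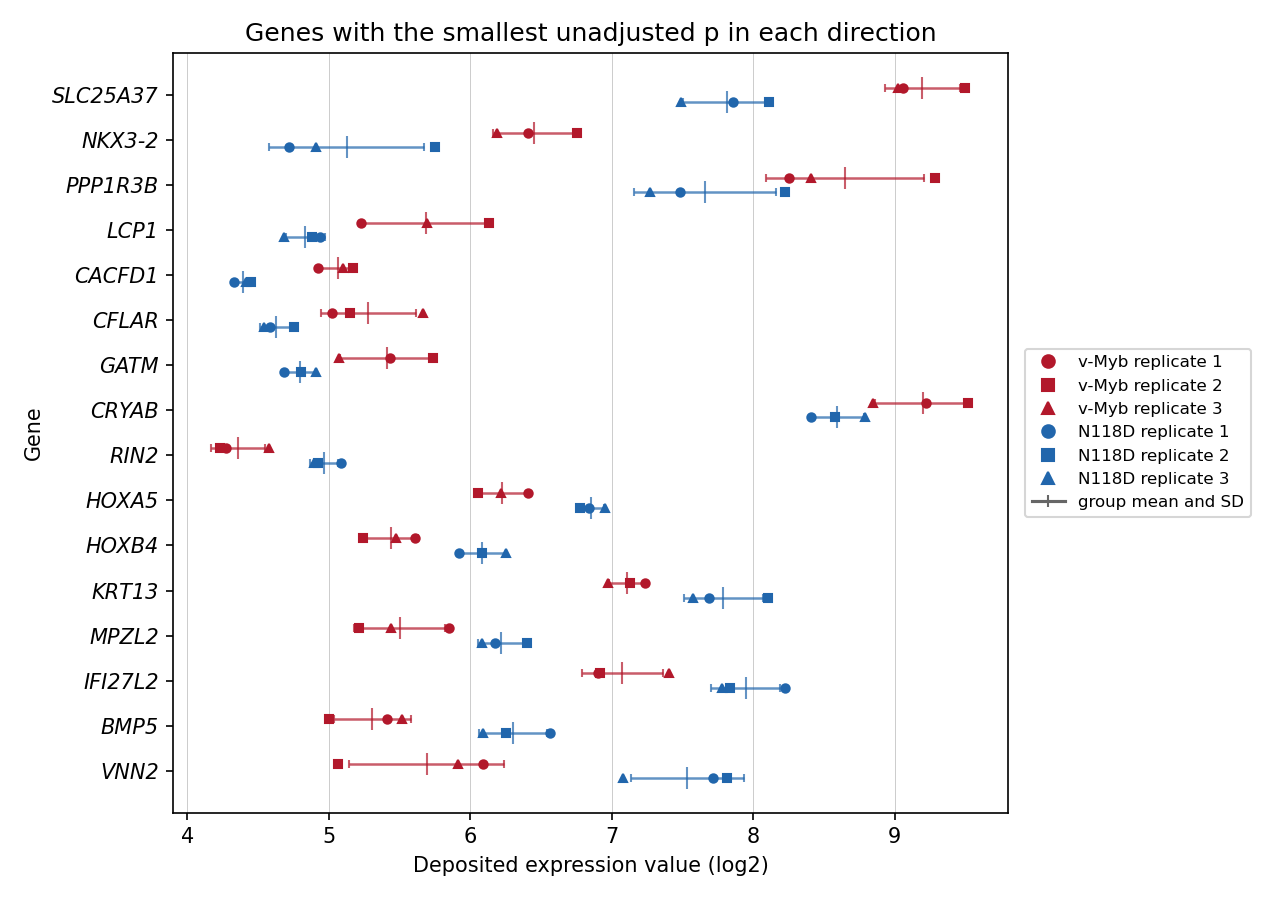
Deposited log2 expression values (horizontal axis) of the 16 genes chosen by the smallest unadjusted p in each direction (vertical axis). Each symbol is an array, red for v-Myb and blue for N118D, and the bars give the group mean and SD (n = 3 each). The groups do not overlap for any of the 16 genes, which the choice by smallest p makes likely, and none passed the adjusted threshold.

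The MYB probe set stayed between 2.16 and 2.20 on all 6 arrays, under the minimum for testing, and whether it covers the part of the gene that v-Myb carries was not established.

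The melanoblast and melanocyte list passed camera's test at a preset correlation with an adjusted p of 5.58e-08, and its adjusted p = 0.724 with an estimated correlation. Of its 19 measured genes 0 passed in limma over all probe sets tested and 0 when adjusted over the list alone, and 1, PMEL, had an unadjusted p under 0.05. The melanosome matrix gene PMEL was at 10.41 ± 0.26 in v-Myb and 9.96 ± 0.21 in N118D cultures (SD, n = 3 each), a difference of 0.45 with a standard error of 0.17. MLANA, a melanosome protein, was higher by 0.53, the melanin synthesis enzyme DCT by 0.38 and tyrosinase, TYR, by 0.48, with standard errors of 0.28, 0.21 and 0.27. The list mean was 0.10 without v-Myb replicate 2 and 0.56 without v-Myb replicate 1. Relative to the mean of all arrays, the list stood at -0.20, 0.72 and 0.03 in v-Myb replicates 1, 2 and 3. It stood at -0.35, -0.08 and -0.12 in N118D replicates 1, 2 and 3, so the groups overlapped. On v-Myb replicate 2 a list of epithelial genes, chosen after the values were seen, had its lowest mean level, 7.48 against 8.19 to 9.24 on the others.

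**Figure D2:**
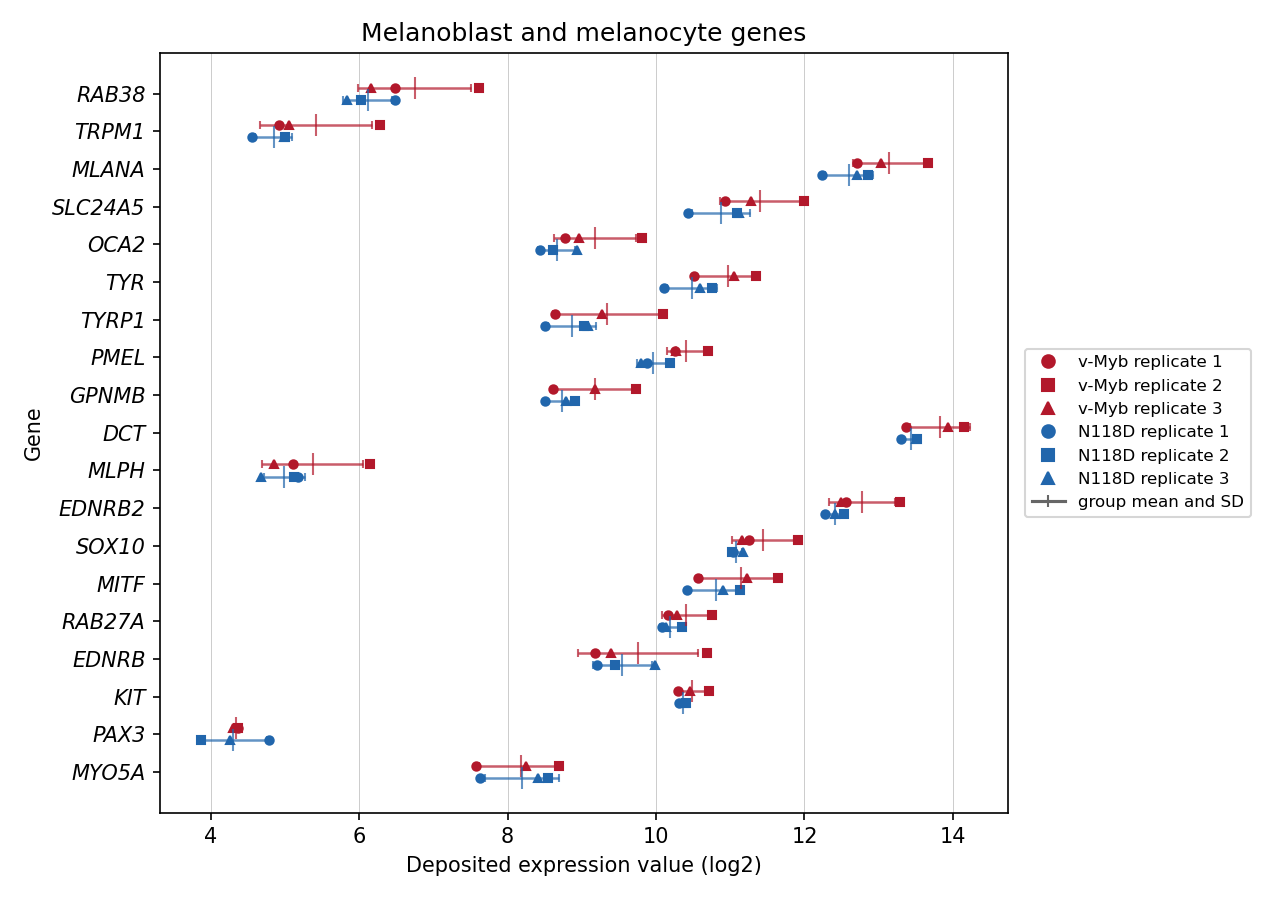
Deposited log2 expression values (horizontal axis) of the 19 measured melanoblast and melanocyte genes (vertical axis), ordered by the difference between groups. Each symbol is an array, red for v-Myb and blue for N118D, and the bars give the group mean and SD (n = 3 each); the means of 18 genes were higher in v-Myb cultures, and v-Myb replicate 2 had the highest value in most of them.

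The neural crest progenitor list, with 13 of 19 genes higher and a mean difference of 0.03, did not pass camera (adjusted p 0.447). Its members with the smallest p were ZIC1, which differed by -0.47, SOX10 by 0.36, RXRG by 0.24 and TFAP2B by 0.26. In v-Myb replicate 2 SOX10 was at 11.92 and TFAP2B at 12.24, against 11.03 to 11.25 and 11.55 to 11.72 on the other arrays. The list mean was -0.021 without v-Myb replicate 2 and -0.0031 without N118D replicate 2. Cell cycle genes were higher in 15 of 26 cases with a mean difference of 0.01 (camera adjusted p 0.665), and E2F1 differed by 0.28, CCNB3 by -0.21, CDKN1A by 0.17 and CCNA2 by 0.08. Of 12 measured genes among 18 annotated reported Myb targets 9 were lower, with a mean of -0.09 (camera adjusted p 0.447) that was -0.16 without v-Myb replicate 1 and -0.035 without N118D replicate 1. The differences were -0.12 for CEBPB, 0.24 for BCL2, -0.39 for TOM1L1 and 0.13 for KIT. TOM1L1 was at 7.22 in N118D replicate 1 and between 5.83 and 6.74 on the other arrays. LECT2, first described in chicken cells as the Myb target mim-1, stayed between 2.35 and 2.62 on all arrays and LYZ between 1.74 and 2.11, and neither was tested.

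The list of BMP ligands, receptors and SMADs passed camera with an adjusted p of 0.0115 at the preset correlation, and its adjusted p = 0.724 with an estimated correlation. BMP5 passed when adjusted over the list alone, with an adjusted p of 0.0197 in limma, and 0 genes passed over all probe sets tested. BMPR1B differed by -0.26, BMP7 by -0.43 and the receptor gene annotated as ATVR1 by -0.10, and a further BMP7 probe set differed by -0.066. The list median was -0.10, nearer to 0 than the mean of -0.19. Without N118D replicate 1 the list mean was -0.12 and camera's adjusted p 0.161, and without v-Myb replicate 2 these were -0.14 and 0.0795, while the adjusted p went down to 0.00205 without N118D replicate 3. Of 9 BMP antagonists 6 were lower, with a mean of -0.21 that did not pass camera (adjusted p 0.187). The antagonist CHRDL1 had levels of 6.88 ± 0.11 and 7.26 ± 0.07 (SD, n = 3 each), a difference of -0.38 that passed when adjusted over the list alone (limma adjusted p 0.0438) but not over all probe sets. SOSTDC1 differed by -1.18 with a standard error of 0.57, FST by -0.33 and CHRD by 0.09. BMP response genes were lower in 8 of 12 cases with a mean of -0.01 (camera adjusted p 0.553), and the transcription factor genes HEY1, ID1, MSX2 and ID2 differed by 0.59, -0.27, -0.27 and -0.10. HEY1 ranged from 6.19 to 7.49 on the v-Myb arrays and from 5.98 to 6.47 on the N118D arrays. Of 3 further ID2 probe sets the differences were -0.37, -0.17 and 0.04.

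Mesenchymal and matrix genes passed camera with an adjusted p of 0.0414 at the preset correlation, and the list's adjusted p = 0.724 with an estimated correlation. The collagen genes COL3A1, COL1A2 and COL5A1 differed by -0.30, -0.19 and -0.23, and the matrix glycoprotein gene SPARC by -0.13. Further COL3A1 probe sets differed by -0.40, -0.069 and -0.0039. TGF-beta pathway genes passed with an adjusted p of 0.0288, and the adjusted p = 0.724 with an estimated correlation. TGIF1, PMEPA1, TGFBR1 and INHBA differed by -0.19, -0.23, -0.11 and -0.22. A further PMEPA1 probe set differed by 0.0062. In both lists 0 genes passed in limma over all probe sets, 0 when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Without N118D replicate 1 the list means were -0.04 and -0.06, and without v-Myb replicate 2 -0.04 and -0.04, with both calls lost. Both calls were also lost without v-Myb replicate 1, where the means were -0.10 and -0.09. The same held without N118D replicate 2, with means of -0.11 and -0.13. The list means grew to -0.22 and -0.21 without v-Myb replicate 3 and, for the mesenchymal list, to -0.22 without N118D replicate 3. The epithelial gene list had a mean difference of -0.84 across the same groups, and of -0.52 without v-Myb replicate 2.

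Markers of neural tissue differed more between arrays than between groups. Neuronal genes were lower in 5 of 9 cases with a mean difference of -0.09 (camera adjusted p 0.976), and relative to the mean of all arrays the list stood at 1.16 in v-Myb replicate 1 and at -0.49 and -0.79 in the other v-Myb arrays. Its mean difference was -0.68 without v-Myb replicate 1, with an adjusted p of 8.54e-05 in camera, 0.14 without v-Myb replicate 2 and 0.29 without v-Myb replicate 3. The neuronal genes TUBB3, NEFL, NEFM and ELAVL4 differed by 0.32, -0.27, -0.33 and -0.27, with standard errors of 0.32 to 0.65. Neural tube progenitor genes were lower in 3 of 6 cases with a mean of -0.33 (camera adjusted p 0.665) and stood at 0.80 in v-Myb replicate 1 and at -0.66 and -0.64 in the other v-Myb arrays, and without v-Myb replicate 1 their mean difference was -0.81 with an adjusted p of 0.0391 in camera, against -0.085 without v-Myb replicate 2. HES5 was at 5.72 ± 3.45 in v-Myb and 7.15 ± 1.03 in N118D cultures (SD, n = 3 each), a difference of -1.43 with a standard error of 1.72. That was the largest difference in this list, whose median was -0.14, and in the Notch list. SOX3, PAX6 and OTX2 differed by -0.33, -0.51 and 0.18. Of 3 glial and Schwann cell genes 2 were lower, with a mean of -0.15 (camera adjusted p 0.447) and differences of -0.28 for MBP, 0.15 for PMP22 and -0.32 for FABP7. Of 8 Notch pathway genes 5 were lower, with a mean of -0.16 and a median of -0.09 (camera adjusted p 0.665). HES4 and LFNG differed by -0.10 and -0.08, beside HEY1 and HES5. The Notch mean was -0.60 without v-Myb replicate 1, 0.017 without v-Myb replicate 2 and 0.10 without v-Myb replicate 3.

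**Figure D3:**
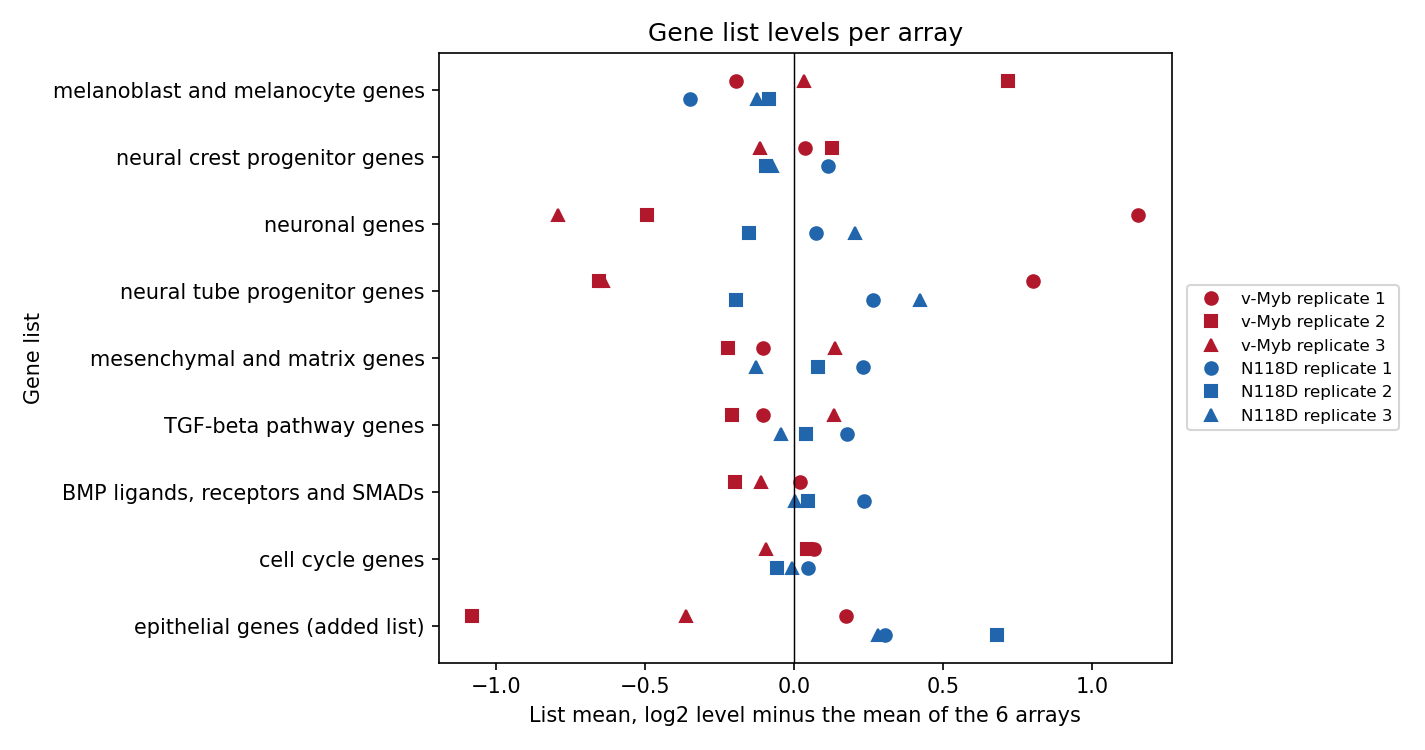
Mean log2 level of each gene list on each array relative to the mean of the 6 arrays (horizontal axis) for 9 lists (vertical axis), the last of them chosen after the values were seen. Each symbol is an array, red for v-Myb and blue for N118D; v-Myb replicate 1 stands at 1.16 for neuronal genes, and v-Myb replicate 2 stands at 0.72 for melanoblast and melanocyte genes.

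With all 6 arrays and the minimum of 4 for testing, none of the remaining lists passed camera. Wnt pathway genes were lower in 9 of 11 cases with a mean of -0.14 (camera adjusted p 0.180), and RSPO3, AXIN2, WNT3A and LEF1 differed by -0.27, -0.25, -0.62 and -0.36. Without v-Myb replicate 1 the Wnt mean was -0.34 and passed, with an adjusted p of 0.00816, and without v-Myb replicate 3 it was -0.032. FGF and MAPK feedback genes were lower in 10 of 13 cases with a mean of -0.09 (camera adjusted p 0.447), and FGF2, ETV5, FGFR2 and ETV1 differed by 0.22, -0.14, -0.41 and -0.06. FGFR2 was at 9.92 in v-Myb replicate 2 and between 10.82 and 11.28 on the other arrays. Without N118D replicate 3 the FGF mean was -0.13 and passed, with an adjusted p of 0.0302, while it was -0.20 without v-Myb replicate 1 and -0.0027 without v-Myb replicate 2. Of 6 interferon response genes 4 were higher, with a median of 0.04 and a mean of -0.11 that differ in sign (camera adjusted p 0.844, direction down). IFI27L2 passed when adjusted over this list alone (limma adjusted p 0.0234), and EIF2AK2, IRF7 and TRIM25 differed by 0.11, 0.08 and 0.05. Stress and immediate early genes were lower in 9 of 13 cases with a mean of -0.03 (camera adjusted p 0.447), and EGR1, HSPB1, HSPH1 and DNAJA1 differed by -0.16, -0.12, -0.07 and 0.11.

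Lists of other mesodermal and blood cell types held few measured genes. Skeletal muscle genes were lower in 3 of 5 cases with a mean of -0.14 (camera adjusted p 0.204), and ACTC1, ACTA1, MYOD1 and TNNT3 differed by -0.38, -0.40, -0.19 and 0.14. Of 4 cartilage genes 3 were lower, with a median of -0.08 and a mean of 0.02 that differ in sign (camera adjusted p 0.676, direction down), and COL2A1, HAPLN1, MATN1 and COL11A1 differed by -0.07, -0.14, 0.39 and -0.09. Further probe sets of COL11A1 differed by -0.24 and 0.15. Of 5 endothelial genes 3 were higher, with a mean of 0.02 (camera adjusted p 0.844), and VWF, ERG, FLI1 and PECAM1 differed by -0.10, 0.12, 0.09 and 0.15, while a further ERG probe set differed by -0.12. The blood and macrophage list had 2 measured genes and a mean of 0.06 (camera adjusted p 0.665), with PTPRC, the pan-leukocyte gene, higher by 0.38 and CD74 differing by -0.26. Camera with an estimated correlation called 0 of the 21 lists, and fry, which asks whether the genes of a list move one way on balance, also called 0.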

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

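The neural score as a covariate and leaving out both arrays numbered 1 were chosen after seeing the data. The count of probe sets past the adjusted threshold was 0 in every alternative run, and the smallest adjusted p in any of them was 0.0553, for UPK3BL (-2.15, chosen after its values were seen), without v-Myb replicate 1, with the others reaching up to 1. The count at an unadjusted p under 0.05, 315 as reported, was 734 without a filter, 202 with the filter at 6, 671 with array weights, 147 with the mean of probe sets per gene, and 560 with the neural score and 1104 without both arrays numbered 1. The change without a filter or with another filter goes with the number of probe sets tested, and the cause of the others was not tested. Leaving out 1 array gave 176 to 1206. The number of lists called, 4 as reported, was 2 without a filter, 2 with the mean of probe sets per gene, 0 with an estimated correlation and 0 with fry, and 1 to 5 leaving out 1 array. Without a filter and with the mean per gene, the mesenchymal list (camera adjusted p 0.146 and 0.127) and the TGF-beta list (0.0874 and 0.05004) lost their calls. Their means moved little, at -0.12 and -0.12 for the mesenchymal and -0.10 and -0.11 for the TGF-beta list. The melanocyte mean of 0.37 did not depend on the test, but lost its call with an estimated correlation (adjusted p 0.724) and with fry (adjusted p 0.913). It kept its call and direction in every other alternative, from 0.10 to 0.56 leaving out 1 array, and the epithelial mean, -0.84 as reported, was -0.56 without a filter, -1.14 to -0.52 leaving out 1 array and -1.20 without both arrays numbered 1. Probe sets at least 2-fold higher and lower, 8 and 52 as reported, numbered 10 and 95 with array weights and 10 and 195 without both arrays numbered 1.

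The groups share replicate numbers. Arrays with the same number had correlations of 0.401, 0.445 and -0.048 in their deviations from the group means, and not every array correlated best with its own number. With the replicate number as a block, 666 probe sets had an unadjusted p under 0.05, 0 passed the adjusted threshold and 2 lists were called, without the mesenchymal (adjusted p 0.0535) and TGF-beta lists (0.0622).

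Of 1615 values of the 102 named probe sets under the alternatives, 1584 kept their direction, 31 reversed it and 0 passed the threshold. Some of these could not reverse. The change of filter, the eBayes settings, no moderation and the replicate block leave the difference of a probe set as it was. Reversals leaving out 1 array had these ranges: TNNT3 -0.045 to 0.27, HAPLN1 -0.37 to 0.027, MATN1 -0.066 to 1.06, PECAM1 -0.13 to 0.67, ELAVL4 -1.01 to 0.15, COL2A1 -0.17 to 0.023, COL11A1 -0.21 to 0.081, DNAJA1 -0.028 to 0.21, IRF7 -0.036 to 0.20, OTX2 -0.097 to 0.45, TRIM25 -0.036 to 0.13, PMP22 -0.026 to 0.30, NEFL -0.84 to 0.12, NEFM -1.10 to 0.14, ERG -0.098 to 0.25 and FLI1 -0.056 to 0.21. Without both arrays numbered 1, TNNT3 was at -0.11, VWF at 0.069 and INHBA at 0.036. PECAM1 was at -0.00441 with the neural score and TNNT3 at -0.00117 with array weights. The cause was not tested.

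List means reversed by leaving out 1 array ranged from -0.021 to 0.10 for crest progenitor, -0.051 to 0.039 for BMP response, -0.020 to 0.061 for cell cycle, -0.68 to 0.29 for neuronal, -0.14 to 0.21 for cartilage, -0.053 to 0.12 for blood, -0.057 to 0.14 for endothelial, -0.093 to 0.024 for stress and -0.60 to 0.10 for Notch genes. Without a filter the glial mean was 0.00591 and the blood mean -0.38, and with the filter at 6 the blood mean was -0.26. Without a filter the blood list also held the globin genes HBAD and HBA1, which were detected on N118D replicate 2 only. With the filter at 6 its mean was that of CD74 alone. The neural score took the neuronal mean to 0.11 and the cartilage mean to -0.038, and leaving out both arrays numbered 1 took BMP response to 0.030 and interferon to 0.020. With the filter at 6, BMP antagonists (-0.25) and Wnt genes (-0.18) were also called, as were BMP antagonists (-0.19) with the neural score. Leaving out both arrays numbered 1, neuronal (-0.67), Wnt (-0.32) and Notch genes (-0.62) were called, and BMP ligands (-0.18), mesenchymal (-0.018) and TGF-beta genes (-0.035) were not. The other list means ranged, leaving out 1 array, from -0.29 to -0.14 for BMP antagonists, -0.25 to -0.12 for BMP ligands, -0.16 to -0.035 for Myb targets, -0.23 to -0.063 for glial, -0.22 to -0.039 for mesenchymal, -0.81 to -0.085 for neural tube, -0.19 to -0.076 for muscle, -0.16 to -0.033 for interferon, -0.34 to -0.032 for Wnt, -0.21 to -0.043 for TGF-beta and -0.20 to -0.0027 for FGF genes. Signal over background limits dim probe sets, and the filter leaves in those near the floor on up to 3 arrays.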

Other observations

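The splits of the 6 arrays for the counts of probe sets and lists, and the neural score test, were set before their results were seen, although the score was added after seeing the data and the bound by which its test was read was set after its result was seen. The tests of 1 array apart, of the epithelial list and of the melanocyte list were chosen after the results they bear on.

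The 52 probe sets that were at least 2-fold lower in v-Myb cultures held 35 genes with 1 symbol. Of these, 9 genes with 15 probe sets belonged to an epithelial list drawn up after the values had been seen. Of its 43 genes 30 had a probe set and 19 were measured, of which 17 were lower in v-Myb cultures, and 0 of the 43 were in a list fixed in advance. The list mean was 8.13 ± 0.63 in v-Myb and 8.98 ± 0.23 in N118D cultures (SD, n = 3 each), a mean difference of -0.84. The genes with a large difference included the keratin KRT14 with -1.49, the cornified envelope gene EVPL with -1.46, the epithelial adhesion gene EPCAM with -1.29, KRT24 with -1.16 and E-cadherin, CDH1, with -1.10, with standard errors of 0.87, 0.42, 0.57, 0.39 and 0.53. Without v-Myb replicate 2 these were -0.63, -0.997, -0.77, -0.78 and -0.65. KRT7 was at 13.55 ± 0.57 against 14.21 ± 0.15 (SD, n = 3 each), and differed by -0.66, or by -0.36 without v-Myb replicate 2. Camera gave the list a p of 4.56e-12 at the preset correlation and a p of 0.0440 with an estimated correlation, fry a p of 0.0622, and 0 members passed the adjusted threshold in limma, with 4 at an unadjusted p under 0.05. Since the list was drawn up after some of these genes had been seen to be lower, these p-values are not independent evidence. AvBD10, an avian beta-defensin, and AGR2, chosen after their values were seen, differed by -4.38 and -2.40 with standard errors of 1.36 and 0.98, and AvBD10 was near the floor at 2.70 in v-Myb replicate 2.

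Globin genes were detected on 1 array. In N118D replicate 2, HBAD probe sets were at 5.91 and 7.29 and HBA1 probe sets at 4.76 and 6.85, where the other 5 arrays lay between 1.89 and 2.83. HBZ was at 5.41 there, against 2.22 to 2.40 on the others. A further probe set of HBA1 and a further one of HBAD were at 2.05 and 1.86 on that array, close to the others. HBA1 and HBAD belong to the blood list fixed in advance but did not reach the minimum for testing. All 3 genes were named here after their values were seen. Probe sets named by a sequence accession numbered 689, of which 3 had a mean of at least 4. The brightest of these, without a symbol, lay between 13.51 and 14.62 on all arrays of both groups, and what it detects was not established.

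Fewer probe sets than chance would give had an unadjusted p under 0.05, 315 against 826. Of the 10 splits of the 6 arrays into groups of 3, 8 gave at least as many and 3 at most as many, the real one in both, which is too few splits to decide. The highest other count, 2477, set v-Myb replicate 1 with N118D replicates 1 and 3 against the rest, the arrays with the highest neural scores (9.40, 8.53 and 8.68), which points to a structure of the samples that the groups do not follow. With the neural score as a covariate the count was 560, under the 826 given by chance. By the rule set beforehand, such a count goes against neural cells in unequal amounts as the cause. By the bound set later it does not decide, as 560 was under 826 by less than the count varies over the splits (115 to 2477). Those splits were fitted without the covariate, so their spread is not the error of this count, and the explanation stays open. Without v-Myb replicate 1, which also had the highest neural score, the count was 1206, so that array may widen the spread within its group. In that fit the neural scores of the v-Myb arrays left (7.83 and 7.65) lay below those of all N118D arrays (8.2 to 8.7). The rise can thus not be told apart from one given by unequal neural cells between the groups. With the replicate number as a block the count was 666, and the titles do not say whether the shared numbers mark shared batches. A real effect of the DNA-binding domain that the spread hides stays open.

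The epithelial list was lower in v-Myb cultures by a mean of 0.84, and 1 of the 10 splits, the real one, gave a mean as far from 0 (0.844, highest other 0.774), which is too few splits to decide. The mean was -0.52 without v-Myb replicate 2, and since the list was drawn up on these same arrays and groups, neither value decides whether the difference goes beyond chance or that array. Within groups the members varied together, with a median r of 0.849 between a member and the mean of the others (from -0.903 to 0.991), as unequal amounts of epithelial cells between cultures could give. The members were chosen on these same arrays, so this r is not independent evidence either. Regulation of these genes by v-Myb was not tested and stays open.

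The melanocyte list mean of 0.37 came down to 0.104 without v-Myb replicate 2, so 1 culture may set most of its size, although the adjusted p in camera at the preset correlation was then 0.0140 (3.73e-09 without v-Myb replicate 1), and with all arrays it was 0.724 at an estimated correlation. Fewer cells of types other than pigment and mesenchymal cells would raise both lists alike. The mesenchymal mean was on the other side of 0, at -0.12 with 16 of 18 genes lower. The difference of the list means was 0.494 with a standard error of 0.387. With 3 arrays per group that explanation thus cannot be told apart from a change in melanocyte genes. A loss that included mesenchymal cells would lower their genes instead and was not tested. More pigment cells, or more pigment gene transcripts per cell, in v-Myb cultures stay open as untested. Of the 10 splits, 4, the real one among them, called at least as many of the fixed lists in camera at its preset correlation (4, highest other 6). With 10 splits no share under 0.05 can arise, so this test could not decide. It does show that groupings other than the real one can give as many calls or more.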
